A study of Homo sapiens with 69 samples.

How the data were processed

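RNA sequencing libraries of T cells sorted as CD8+ from the blood of patients after hematopoietic cell transplantation were analysed. There were 69 libraries from 42 patients, taken at day 21 (37 libraries) or day 28 (32 libraries). Of the patients, 27 had both days, 10 had day 21 only and 5 had day 28 only. Per the labels' protocols, patients belonged to the placebo arm of a clinical trial, cDNA was made from a low RNA input with a template-switching kit, libraries were made by tagmentation, and reads were single-end. The labels name CD8+ cells for every library, while the RNA protocol speaks of both CD4 and CD8 sorted cells. Levels of marker genes of both are therefore given with the results. No outcome, batch or run was given in the labels used here.

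The authors deposited 1 table of normalized values for 19644 rows with gene symbols, treated here as a signal that is never negative. Per the submitters' processing notes, the tools were Trimmomatic, kallisto 0.46.1 and DESeq2, with the build GRCh38.p13; the role of each tool was not given in the sources used here. Between 20.8% and 27.4% of the low values of a library (median 23.9%) were whole multiples of its value step, within a tolerance of 0.01 of a step. Whether the others come from fractional estimates of reads or from a factor per gene was not tested. Whole reads could not be recovered, and the planned count model on recovered reads was not run. Steps between low values gave a relative depth per library of 0.351 to 1.73 (median 1.06), or roughly 6190000 to 32780000 reads (median 20470000). Fold changes of low genes are less certain in the shallower libraries.

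Rows that shared a symbol (1934 repeats, mostly alternate loci) were summed. Rows of the Y chromosome, XIST and TSIX (14) were left out of all tests, leaving 17696 symbols. Reads of near-identical genes, such as HBA1 and HBA2, and of read-through genes, as at NME2 and ST20, can be split by the authors' counting, so values of these genes are uncertain.

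Comparisons, gene lists and the rule for named genes were fixed before the data were examined. Day 28 was compared with day 21 with limma 3.58.1 in R 4.3.3 (trend and robust options) on log2(value + 1), with the patient as a fixed block, over the 54 libraries of the 27 patients with both days. The labels give the patient of each library, which is where the pairing comes from; the consensus correlation of libraries of a patient was 0.327. Genes with a value of at least 10 in at least 27 of the 54 libraries were tested (13052 genes). P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are on the log2(value + 1) scale, which understates changes of low genes.

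For 28 gene lists (544 genes, of which 538 had a row and 505 were measured after the filter), a score was the mean of log2(value + 1) over measured members. Paired changes of scores were tested with a two-sided sign-flip permutation test with 100000 resamples, adjusted over the 28 lists. Scores of 10 lists were related to the cell cycle score, the mean of the S phase and G2 and mitosis scores, across patients at day 21, at day 28 and for the paired change (30 relations, adjusted together). Scores at day 21 were also related to the same scores at day 28 for the 28 lists. These used Pearson's r and Spearman's rho with two-sided permutation p-values; the smallest p these can give is 1e-05. P-values of partial correlations and of list changes with covariates came from the linear model, in which the error of the covariates' slopes counts. The exception is the cytotoxic score given the naive and central memory score, whose permutation p came from permuted residuals. Taking slopes out before sign-flips gave p under 0.05 for 34% of simulated lists with no change, against 4.65% for the linear model, so the former was not used. That replacement was made after list changes with covariates had been seen: 6 lists passed with the marker scores as covariates before it and 0 after it. Relations of single list members to the cell cycle score (449 members, adjusted together at each day) were computed after the list relations were seen.

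Named genes were to be the 15 largest rises and falls past the threshold with a mean value of at least 50, or, with fewer than 20 past it, the 20 with the smallest p, and up to 4 members of each list by smallest p. From a list with no member past the threshold, adjusted over the list alone, at most 2 were to be named. Members named for their relation to the cell cycle score were those with the largest absolute r at day 21 among those past the threshold. HLA genes other than HLA-DRA, KIR genes and antigen receptor segments were not named. The result of 1 further list member is not reported here. Gene coordinates are from GENCODE 29 on GRCh38. Lengths and GC content of transcripts, from the same source, were available for 12627 genes tested (96.7%).

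The gene test was tested on simulated data for 13052 genes and 27 pairs with 200 genes changed: 59.3% of changes of 0.5 on the log2 scale, 84.7% of 1, 96.0% of 1.5 and 100% of 2.0 were recovered, with 5.21% false calls among the calls and 0 calls where nothing was changed. Noise was drawn independently for each gene and the changed genes were picked at random, while real genes vary together. Recovery in the real data can therefore differ, and can be lower for genes with a large SE. The list test gave p under 0.05 for 5.9% of simulated lists with no change. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

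Alternatives were other pseudocounts (5 and 0.1), filters, scalings, library weights, covariates, the sign-flip test per gene, set tests (camera and fry), fits without the replicate block or with the patient as a random block, and each patient left out in turn. Chosen after seeing the data were relative depth and the change in genes detected as covariates, leaving out the pairs of the shallowest library and of the library with the highest share of its top 20 genes, rows kept apart, removal of a length and GC trend, and the marker scores of monocytes, platelets and erythroid cells as covariates, alone and with that of CD4 T cells.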

Results

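Transcriptomes of sorted CD8+ T cells were measured in blood of patients recovering from hematopoietic cell transplantation, in which donor T cells expand in the recipient. Libraries were taken at day 21 (n = 37) and day 28 (n = 32) after transplantation. Sums of deposited normalized values were 17664827 to 24917265 per library, and 14702 to 16272 gene symbols were above 0. The relative depth, estimated from the steps between low values, did not differ detectably between the days of the 27 paired patients (log2 change -0.15 ± 0.09 (SE), permutation p = 0.127). Patients differed widely in proliferation: the G2 and mitosis score at the 90th percentile of patients was 16.9-fold that at the 10th percentile at day 21 and 6.09-fold at day 28. CD8A had a median value of 22108 at day 21 and 25447 at day 28, and CD4 had 161 and 223.

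The first comparison asked how CD8+ T cells of the same patient differed between day 21 and day 28. The gene with the smallest p was IL2RA, the alpha chain of the interleukin 2 receptor, with a mean value of 122 ± 74.6 (SD) at day 21 and 68.4 ± 54.1 at day 28 (log2 fold change -0.97 ± 0.20 (SE), n = 27 pairs, lower in 24 patients). ZEB2, a transcription factor of terminal effector T cells, had a mean of 1519 at day 21 and 2641 at day 28 (log2 fold change 0.82 ± 0.17, higher in 21 patients). E2F1, a transcription factor of S phase entry, had means of 547 and 248 (-0.90 ± 0.21, lower in 22 patients). None of these passed the threshold: of 13052 genes tested with limma with the patient as a block, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.146. At an unadjusted p under 0.05 there were 1829 genes (14.01%), 818 higher and 1011 lower at day 28. The per-gene sign-flip permutation test called 9 genes: IL2RA, PYCR1, ATIC, THOC6, ST20, MRPL14, TIMM13 and LRP5 lower and GPCPD1 higher, of which LRP5 is named after its values were seen. The fit with the patient as a random block over all 69 libraries called 1 gene, ST20, lower.

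Of the 20 genes with the smallest p, 14 were lower at day 28 and 6 were higher, none past the adjusted threshold with limma. Among the lower ones were PYCR1, an enzyme of proline synthesis (-1.11 ± 0.26), RMI2, of the complex that dissolves recombination intermediates (-0.87 ± 0.20), and ATIC, of purine synthesis (-0.30 ± 0.07, lower in 24 patients). Genes of mitochondrial proteins were CLPP (-0.30 ± 0.07), MRPL14 (-0.29 ± 0.07), TIMM13 (-0.38 ± 0.09) and TXN2 (-0.27 ± 0.06). The others lower were ST20 (-0.51 ± 0.12), THOC6 (-0.29 ± 0.07), NME2 (-0.36 ± 0.09), SNRPD2 (-0.26 ± 0.06) and PRKAR1B (-0.36 ± 0.09). Besides ZEB2, values were higher for ARRDC3 (0.45 ± 0.10), SLC15A4 (0.41 ± 0.09), NSMF (0.37 ± 0.09), GPCPD1 (0.36 ± 0.08) and SCAMP1 (0.30 ± 0.07). On GRCh38, IL2RA lies on chromosome 10 from 6010689 to 6062370, ZEB2 on chromosome 2 from 144364364 to 144524583, and E2F1 on chromosome 20 from 33675683 to 33686404, all protein-coding genes on the minus strand.

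**Figure D1:**
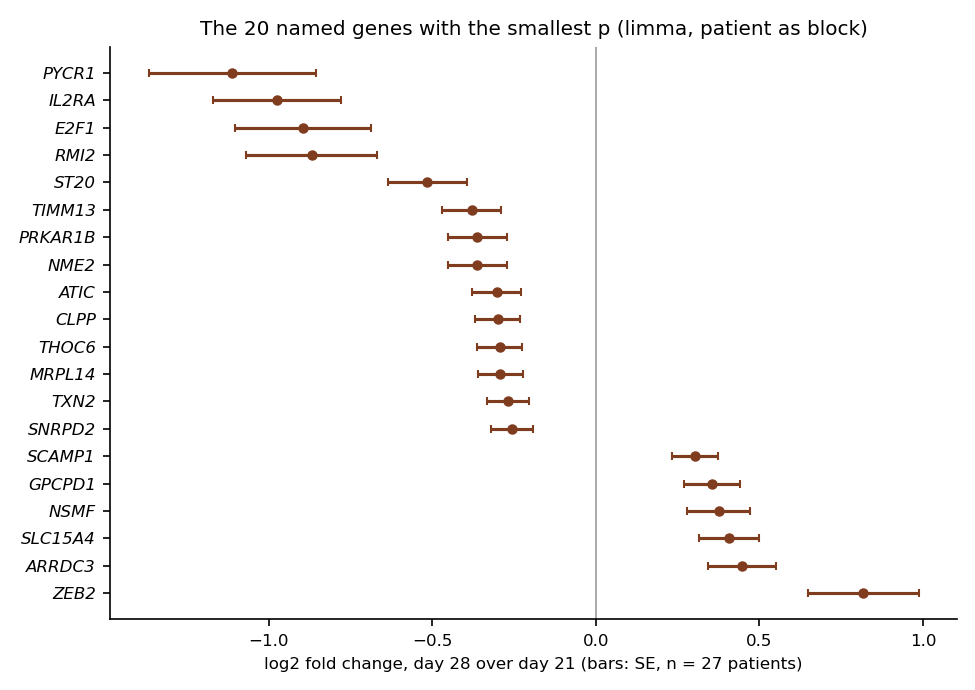
Log2 fold change, day 28 over day 21, of the 20 genes with the smallest p (limma with the patient as a block). Points are estimates and bars are SE over 27 patients; values run from -1.11 for PYCR1 to 0.82 for ZEB2, and none passed the adjusted threshold.

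Members of both cell cycle lists had estimates below 0, lower at day 28. The S phase score changed by -0.71 ± 0.27 (SE, log2, n = 27), lower in 22 patients, and its 24 measured members all had estimates below 0. Adjusted over the list alone, 20 of the 24 passed and 0 passed over all genes. Among them GINS2, of the replicative helicase, fell by 1.10, CDT1, which licenses origins, fell by 0.93, and MCM6 fell by 0.52 on the log2 scale, adjusted over the list alone. The G2 and mitosis score changed by -0.63 ± 0.31, with all 32 members below 0 and 0 past the threshold over the list alone; CCNB2 had -1.17 ± 0.40 and PLK1 -1.18 ± 0.44. Neither score passed the threshold over the 28 lists (permutation p = 0.0122 with adjusted p = 0.125 for S phase, p = 0.0493 with adjusted p = 0.230 for G2 and mitosis). Members varied together, with a correlation between genes, estimated by camera, of 0.80 for S phase and 0.72 for G2 and mitosis. Counts of members are therefore not counts of independent observations. The transcript length trend also differed between the days: the slope of log2 values on length was higher at day 28 by 0.0309 ± 0.0114 (permutation p = 0.0122, higher in 19 patients).

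Scores of energy metabolism and of the p53 response did not pass over the 28 lists, while some of their members fell when adjusted over the list alone. The oxidative phosphorylation score changed by -0.13 ± 0.05 (lower in 21 patients, permutation p = 0.0134, adjusted p = 0.125); 26 of 28 members were below 0 and 11 fell, adjusted over the list alone. ATP5MC3 had -0.28 ± 0.08, NDUFB3 -0.33 ± 0.10, ATP5F1A -0.22 ± 0.07 and ATP5F1C -0.17 ± 0.06. Of 19 glycolysis genes, 4 fell when adjusted over the list alone, ENO1 (-0.32 ± 0.09), HK1 (-0.20 ± 0.06), TPI1 (-0.31 ± 0.09) and PKM (-0.25 ± 0.09), while the score did not pass (-0.09 ± 0.05, adjusted p = 0.290). The p53 response score had the smallest p of the 28 lists (-0.18 ± 0.06, lower in 21 patients, permutation p = 0.00275, adjusted p = 0.0770). BAX, which opens the outer mitochondrial membrane in apoptosis, was its 1 member that fell over the list alone (-0.27 ± 0.08), and FDXR had -0.41 ± 0.14. With members scaled to an SD of 1, or with a pseudocount of 5, this score passed.

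In lists of T cell state few members passed when adjusted over the list alone. Of 18 cytotoxic effector genes, 3 rose when adjusted over the list alone: ZEB2, FGFBP2 (0.60 ± 0.18) and S1PR5 (0.61 ± 0.19), while GZMB, granzyme B, had -0.47 ± 0.20 and did not pass. The score changed by 0.21 ± 0.15 (adjusted p = 0.340). Among 18 activation genes IL2RA and CD70 (-0.61 ± 0.19) fell over the list alone, with DPP4 at -0.47 ± 0.18 and SLAMF7 at 0.38 ± 0.15 not past it (score -0.13 ± 0.08, adjusted p = 0.319). CD160, a receptor of effector lymphocytes, rose over the list alone (0.91 ± 0.26, higher in 22 patients) as 1 of 15 inhibitory receptor genes, and TOX had 0.37 ± 0.14 (score 0.09 ± 0.09, adjusted p = 0.539). The chemokines CCL5 (0.53 ± 0.17) and CCL4 (0.59 ± 0.20) rose over the list alone among 16 cytokine genes, with LTB at -0.46 ± 0.20 (score -0.01 ± 0.08, adjusted p = 0.950). No member passed, adjusted over the list alone, in the naive and central memory list (score -0.20 ± 0.13, adjusted p = 0.340; TXK -0.52 ± 0.21), the tissue residency list (0.11 ± 0.06, adjusted p = 0.266; KLF3 0.42 ± 0.15) or the homing list (-0.22 ± 0.16, adjusted p = 0.340; CCR8 -1.22 ± 0.44).

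The remaining lists of cell programmes did not pass either, and had 0 members past the threshold over the list alone. The type I interferon score changed by -0.30 ± 0.16 (adjusted p = 0.266), with 22 of 25 members below 0, OAS3 at -0.60 ± 0.21 and ISG15 at -0.35 ± 0.12. Scores changed by -0.04 ± 0.09 for the interferon gamma response, 0.21 ± 0.26 for immediate early genes, -0.10 ± 0.07 for heat shock genes and 0.09 ± 0.10 for the glucocorticoid response. They changed by 0.01 ± 0.05 for cholesterol synthesis, -0.03 ± 0.08 for cytosolic ribosomal proteins, 0.00 ± 0.07 for the unfolded protein response and -0.01 ± 0.14 for mitochondrially encoded mRNAs. Adjusted p-values of these 8 lists were 0.340 to 0.950. Camera with a preset correlation called 13 of the 28 lists, among them S phase and oxidative phosphorylation; none held with an estimated correlation, where the smallest adjusted p = 0.398 with an estimated correlation.

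**Figure D2:**
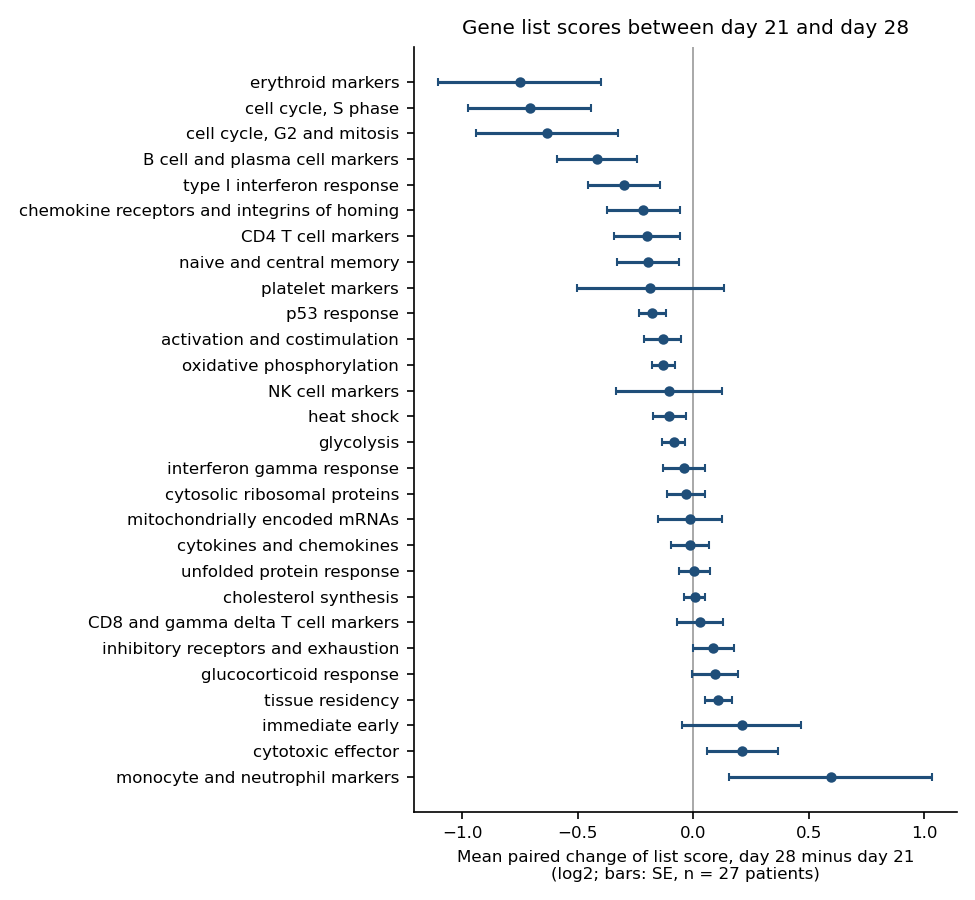
Mean paired change of each of the 28 gene list scores, day 28 minus day 21, on the log2 scale. Points are means and bars are SE over 27 patients; the S phase score lies at -0.71 and the p53 response score at -0.18, and no list passed the adjusted threshold.

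Markers of other blood cells were present in the sorted fraction. LYZ, lysozyme of monocytes and neutrophils, had a median of 2286 at day 21 and 4572 at day 28, and HBB, beta globin, had 2450 and 1233. The erythroid score at the 90th percentile of patients was 53.4-fold that at the 10th percentile at day 21, and the monocyte and neutrophil score 30.8-fold. Between the days the erythroid score changed by -0.75 ± 0.35 (adjusted p = 0.230), with HBD (-1.26 ± 0.44) and CA1 (8 patients higher, 18 lower) lower over the list alone. The monocyte and neutrophil score changed by 0.59 ± 0.44 (adjusted p = 0.340) and the platelet score by -0.19 ± 0.32 (adjusted p = 0.799). The B cell and plasma cell score, with 6 of 15 genes measured, changed by -0.42 ± 0.17 (adjusted p = 0.157). MZB1 (-0.78 ± 0.20) and CD79B (-0.51 ± 0.19) were lower over the list alone. At day 21 both rose with the cell cycle score across patients (r = 0.63 and 0.54), while CD79A of the same list fell (-0.69). Whether the lower MZB1 and CD79B came from fewer B cells was not tested. Scores of NK cells (-0.11 ± 0.23), CD4 T cells (-0.20 ± 0.14) and CD8 and gamma delta T cells (0.03 ± 0.10) had adjusted p-values of 0.831, 0.340 and 0.920. With the changes in the monocyte, platelet and erythroid scores as covariates, 0 of the 25 other lists passed. With the CD4 T cell score as a further covariate, an alternative chosen after the results were seen, 3 of the 24 other lists passed: S phase (-0.96, adjusted p = 0.0202), oxidative phosphorylation (-0.18, adjusted p = 0.0202) and G2 and mitosis (-0.84, adjusted p = 0.0442). The CD4 T cell score may not measure the share of CD4 T cells alone: mean values at day 21 were 7682 for CD5 and 339 for CD4. At day 21, 7 of its 9 genes had a negative r past the threshold with the cell cycle score. These 3 calls therefore do not show a change at a fixed share of CD4 T cells.

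The second comparison asked which programmes varied together with proliferation across patients. At day 21 (n = 37) patients with a higher cell cycle score had a lower naive and central memory score (Pearson r = -0.74, rho = -0.71, both permutation p = 1e-05, the smallest possible, adjusted p = 0.00015) and a higher oxidative phosphorylation score (r = 0.72, p = 1e-05, rho = 0.69, p = 2e-05, adjusted p of r = 0.00015). Scores were also higher for glycolysis (r = 0.63, rho = 0.59), inhibitory receptors (r = 0.60, rho = 0.58), cytotoxic effector genes (r = 0.57, rho = 0.53) and activation (r = 0.45, rho = 0.42). The glucocorticoid response score was lower (r = -0.58, rho = -0.55). These 5 had permutation p-values of r from 4e-05 to 0.00523 and of rho from 0.0002 to 0.00987, with adjusted p-values of r from 0.0004 to 0.0131, and the 7 relations held without the 2 patients farthest from the median. Tissue residency (r = 0.15, rho = 0.03), homing (r = 0.07, rho = -0.02) and type I interferon scores (r = 0.16, rho = 0.22) were not related to it (adjusted p = 0.456 to 0.799).

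At day 28 (n = 32), 5 relations passed: oxidative phosphorylation (r = 0.59, rho = 0.43), naive and central memory (r = -0.54, rho = -0.54), the glucocorticoid response (r = -0.50, rho = -0.41), cytotoxic effector genes (r = 0.46, rho = 0.50) and glycolysis (r = 0.43, rho = 0.35). Their permutation p-values were 0.00043 to 0.0139 for r and 0.00185 to 0.0491 for rho, with adjusted p-values of r from 0.00161 to 0.0278. By rho, 4 of them passed and glycolysis did not (adjusted p = 0.0982), nor did it with values rescaled to a fixed total (r = 0.38, adjusted p = 0.0640). The calls rested on the 2 patients farthest from the median cell cycle score. Without them (n = 30) 0 passed, while r kept its sign, at 0.39, -0.42, -0.42, 0.41 and 0.31 in the same order, with adjusted p-values of 0.0641 to 0.184. Of the paired changes (n = 27), 3 passed. Glycolysis (r = 0.69, p = 0.00016, adjusted p = 0.000814, rho = 0.50, p = 0.00957) kept its call without the 2 farthest patients (r = 0.49). Oxidative phosphorylation (r = 0.63, p = 0.00098, adjusted p = 0.00327, rho = 0.35, p = 0.0720) had r = 0.25 without them, and the glucocorticoid response (r = -0.47, p = 0.0131, adjusted p = 0.0278, rho = -0.46, p = 0.0174) had r = -0.24. Given the marker scores of monocytes, platelets and erythroid cells, all 7 relations at day 21 and all 5 at day 28 stayed past the threshold. That of the paired change in the glucocorticoid response did not (partial r = -0.33, adjusted p = 0.170), and that in the naive and central memory score passed (partial r = -0.48, adjusted p = 0.0344). With the CD4 T cell score given as well, chosen after the results were seen, 3 relations passed at day 21 and 3 at day 28. Glycolysis (partial r = 0.54 and 0.52) and oxidative phosphorylation (0.47 and 0.51) were among them at both days, inhibitory receptors (0.43) at day 21 and the glucocorticoid response (-0.48) at day 28. The other 4 relations no longer passed at day 21: activation (0.42, adjusted p = 0.0520), naive and central memory (-0.40, adjusted p = 0.0633), cytotoxic effector genes (0.36, adjusted p = 0.0900) and the glucocorticoid response (-0.30, adjusted p = 0.171). At day 28 the naive and central memory (-0.39, adjusted p = 0.0900) and cytotoxic scores (0.34, adjusted p = 0.145) no longer passed, nor did the paired change in the glucocorticoid response (-0.13, adjusted p = 0.679).

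**Figure D3:**
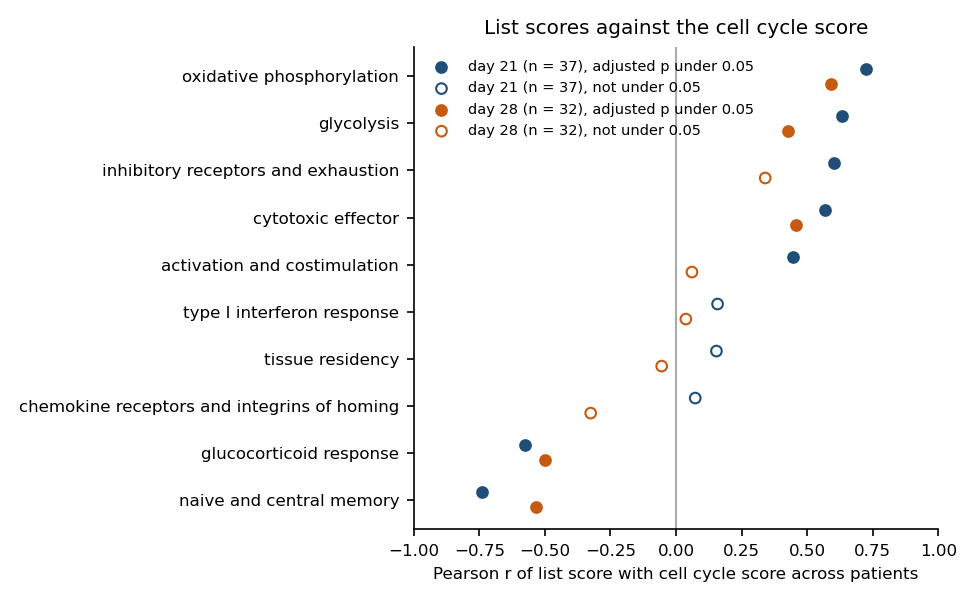
Pearson r of 10 list scores with the cell cycle score across patients at day 21 (blue, n = 37) and day 28 (orange, n = 32). Filled points passed an adjusted p of 0.05; r ran from -0.74 for naive and central memory to 0.72 for oxidative phosphorylation at day 21.

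Single members showed which genes carried these relations. The share past the threshold over all genes tested was not computed, so counts of members do not set a list apart from other genes. At day 21, 15 of 19 naive and central memory genes had a negative r past the threshold, among them NELL2 (r = -0.79), IL7R, the interleukin 7 receptor (-0.76), and ACTN1 (-0.75), and 9 passed at both days. In the cytotoxic list 12 of 18 had a positive r past the threshold, with GZMB (0.72) and GZMA (0.72), and 7 passed at both days. Of 18 activation genes, 8 had a positive r past the threshold at day 21 and 1, TNFRSF4, a negative one (-0.43). CD38, an ectoenzyme of activated T cells, had r = 0.79 at day 21 and 0.77 at day 28. IL2RA, given here for its small p between the days, went the other way. Its r was -0.34 at day 21, not past the threshold, and -0.50 at day 28, past it. Of 15 inhibitory receptor genes, 8 had a positive r past the threshold at day 21, among them the checkpoint receptors LAG3 (0.74), HAVCR2 (0.66), PDCD1 (0.65) and TIGIT (0.62). In the same list VSIR had a negative r past the threshold (-0.54), and 1 gene passed at both days. Among oxidative phosphorylation genes 22 of 28 passed, with ATP5MC3 (0.83 at day 21, 0.69 at day 28) and COX5A (0.83 and 0.73). GAPDH had 0.90 and 0.72 and PGAM1 0.84 and 0.62, while ALDOC of the same glycolysis list had -0.77 and -0.59. TXNIP (-0.83 at day 21; -0.24 at day 28, not past the threshold) and PIK3IP1 (-0.83 and -0.55) led the glucocorticoid list. Marker genes of other cells also moved with the cell cycle score at day 21: 13 of 20 monocyte and neutrophil genes, 7 of 15 platelet genes and 5 of 8 erythroid genes had a negative r past the threshold, and 0 of each at day 28. Of 9 CD4 T cell marker genes, 7 had a negative r past the threshold at day 21, led by FHIT (-0.71) and TNFRSF25 (-0.67), and 1 at day 28. Whether these relations of marker genes differed between the days was not tested. Fewer patients were measured at day 28 (n = 32) than at day 21 (n = 37), so the lower counts do not show that the relations were lost.

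The third comparison asked which programmes kept their order among the 27 patients over the 7 days. Scores at day 21 and day 28 were related for 17 of 28 lists. The highest r was that of the cytotoxic effector score (r = 0.78, permutation p = 1e-05, rho = 0.71, p = 8e-05, adjusted p of r = 0.00028). Cytokines (r = 0.74, rho = 0.77), inhibitory receptors (r = 0.71, rho = 0.75) and naive and central memory (r = 0.71, rho = 0.80) each had an adjusted p of 0.00042. Cholesterol synthesis (r = 0.67, rho = 0.72), CD8 and gamma delta T cell markers (r = 0.64, rho = 0.64), tissue residency (r = 0.60, rho = 0.60) and activation (r = 0.58, rho = 0.58) had adjusted p-values of 0.000784 to 0.00543. The other 9 lists had r from 0.42, for G2 and mitosis, to 0.55, for platelet markers, with adjusted p-values up to 0.0480. Of these 9, mitochondrially encoded mRNAs (r = 0.45, rho = 0.23, adjusted p of rho = 0.269), the p53 response (r = 0.45, rho = 0.27, adjusted p of rho = 0.195) and NK cell markers (r = 0.46, rho = 0.41, adjusted p of rho = 0.0593) did not pass by rho, while the unfolded protein response passed by rho alone (rho = 0.45, adjusted p = 0.0395; r = 0.22, adjusted p = 0.307), so 15 lists passed by rho. The S phase score (r = 0.37, rho = 0.33, adjusted p = 0.0767), oxidative phosphorylation (r = 0.32, rho = 0.39), type I interferon (r = 0.25, rho = 0.41), glycolysis (r = 0.14, rho = 0.28) and homing scores (r = -0.10, rho = -0.02) did not pass. Without the 2 patients farthest from the median day 21 score, 11 lists passed, the 8 lists named first among them. The mitochondrially encoded mRNAs then had r = 0.01, NK cell markers 0.28 and the interferon gamma response 0.38.

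**Figure D4:**
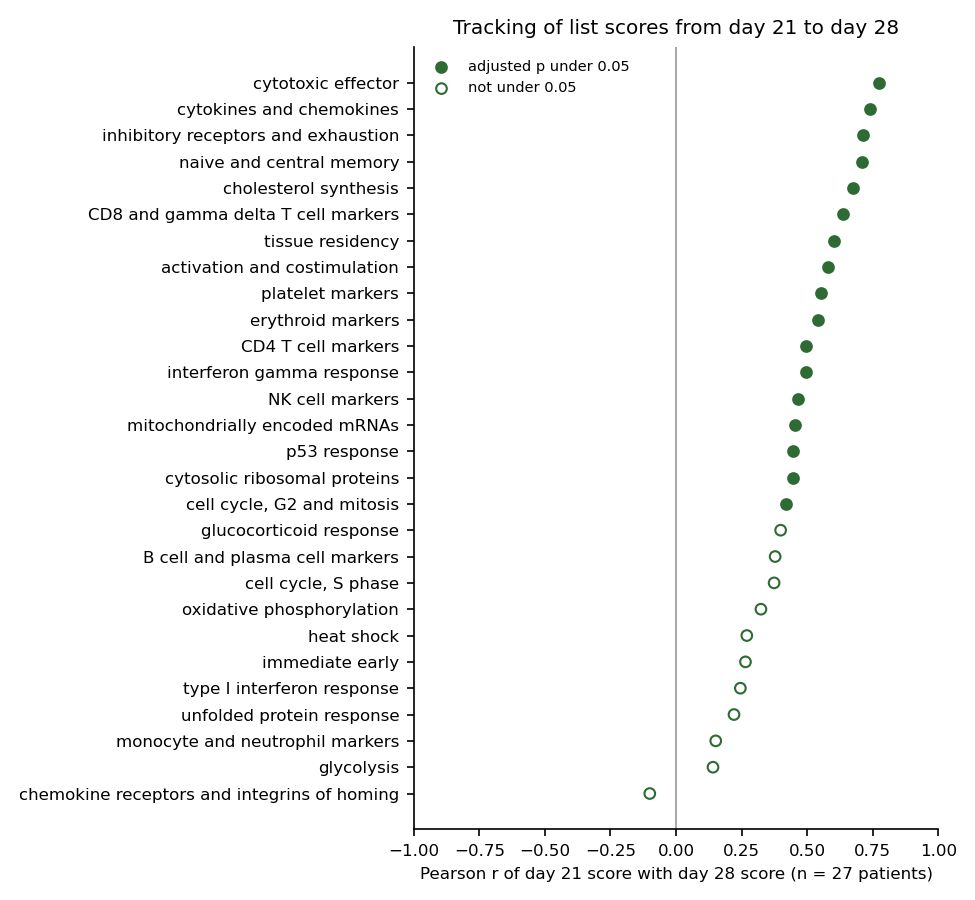
Pearson r between the score at day 21 and the score at day 28 for each of the 28 lists across 27 patients. Filled points passed an adjusted p of 0.05; r ran from -0.10 for homing to 0.78 for cytotoxic effector genes.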

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

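Chosen after seeing the data were the tests with relative depth, the change in genes detected or the marker scores as covariates, those without 2 doubted pairs, with rows kept apart and with a length and GC trend taken out. With limma, 0 genes passed under each alternative except the patient as a random replicate block over all 69 libraries (1 gene, ST20, lower). The sign-flip permutation test per gene called 9 genes, IL2RA among them. Without the replicate block 0 passed, with 1049 genes at an unadjusted p under 0.05 for all 69 libraries and 830 for the 54 paired libraries, against 1829 with it; leaving out each patient in turn gave 1469 to 2284. The count of lists past the threshold was 0, but 1 (p53 response) with a pseudocount of 5 or with members scaled to SD 1, 13 with camera at a preset correlation, and 0 to 3 with each patient left out in turn. It was 3 with the CD4 T cell score added to the marker scores as covariates: S phase (-0.96), G2 and mitosis (-0.84) and oxidative phosphorylation (-0.18). S phase (-0.85, adjusted p = 0.0175) and oxidative phosphorylation (-0.16, adjusted p = 0.0175) passed without 1 patient; over the patients left out, their changes ranged up to -0.57 and -0.10. Related to the cell cycle score were 15 of 30 relations, and 13 by rho, 14 with a fixed total, 8 without the 2 farthest patients and 8 given the marker scores with that of CD4 T cells. Tracking passed for 17 lists, for 15 by rho, and for 11 without the 2 farthest patients. Except for the preset correlation, which ignores the measured correlation of members, and for fewer patients, the cause was not tested.

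Directions turned only where neither value passed. Cytokines turned to 0.0028 centred on the median gene, 0.016 with depth, 0.022 with the marker scores, 0.012 without the doubted pairs and -0.038 to 0.025 leaving out each patient. Mitochondrial mRNAs turned to 0.0025 centred, 0.0025 with depth, 0.072 with the marker scores, 0.0040 with the length and GC trend taken out and -0.087 to 0.027 leaving out each patient. Cholesterol synthesis turned to -0.017 with depth, -0.021 with the marker scores and -0.016 leaving out a patient. The unfolded protein response turned to -0.0086 unfiltered, -0.020 scaled, -0.017 without the replicate block, -0.00094 with the marker scores and -0.045 to 0.024 leaving out each patient. The glucocorticoid response (-0.0043) and CD8 and gamma delta T cell markers (-0.0031) turned without the block, the latter also without the doubted pairs (-0.0070). With the CD4 T cell score added to the marker scores, cytokines turned to 0.072, mitochondrial mRNAs to 0.12, cholesterol synthesis to -0.061 and the unfolded protein response to -0.037. NK cell markers turned to 0.019, from -0.18, leaving out each patient and platelet markers to 0.052 with depth. Relations to the cell cycle score turned for homing at day 21 (rho = -0.023) and type I interferon at day 28 without the 2 farthest patients (-0.086). For paired changes, the marker scores turned cytotoxic (-0.055, or -0.086 with the CD4 T cell score) and activation (-0.032) scores, and leaving out the 2 farthest turned naive (0.064), tissue residency (0.027) and homing (0.22) scores. Homing also turned by rank (0.0055), given genes detected (0.018) and with a fixed total (0.018), and type I interferon given genes detected (-0.016). Of 1663 alternative values for 93 named genes, 1654 kept direction and side of the threshold and 9 passed it.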

Other observations

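The tests of library depth, of the length and GC trend and of the marker scores below were chosen after results were seen, as was the choice of the lists in this paragraph. Outside the 10 lists related to proliferation by design, cytosolic ribosomal protein genes were lower in patients with a higher cell cycle score: 23 of 28 had a negative r past the threshold at day 21 (n = 37), led by RPL3 (r = -0.74 at day 21, -0.58 at day 28), and 10 passed at both days (n = 32 at day 28). Genes of the unfolded protein response went the other way, 14 of 21 at day 21, with the endoplasmic reticulum chaperones DNAJB11 (0.86 at day 21), SDF2L1 (0.85) and PDIA6 (0.83). At day 28, 7 passed with a positive r, PDIA6 (0.57) among them, while DNAJB11 (0.42) and SDF2L1 (0.39) did not pass; XBP1 of the same list had a negative r at both days (-0.59 and -0.52). A positive r past the threshold was also found at day 21 for 13 of 22 interferon gamma response genes, led by the proteasome activator PSME2 (0.75 and 0.61), with 10 past the threshold at both days, while the type I interferon list had 2 of 25 at day 21. Of 20 cholesterol synthesis genes 10 had a positive r past the threshold at day 21, with EBP (0.86 and 0.60) and FDPS (0.74 and 0.65). The share past the threshold over all genes tested was not computed. Counts of list members therefore do not set these lists apart from other genes. IFNG, interferon gamma, had 0.81 and 0.53, and the lymphotoxin genes LTA (-0.65 and -0.52) and LTB (-0.64 and -0.52) had a negative r.

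Between the days, the relation of 2 lists to the cell cycle score differed at an unadjusted level in the 27 pairs: activation by -0.47 (permutation p = 0.0107) and homing by -0.58 (p = 0.0190). Both had an adjusted p of 0.0950 over 10 lists.

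Lower S phase genes at day 28 came with 1829 genes at an unadjusted p under 0.05. Of 100 swaps of the days within pairs, the real one included, 1 reached that number (highest other 1502). Such a count was thus uncommon among swaps, but 100 swaps cannot exclude chance. For the count of 0 genes past the adjusted threshold swaps decide nothing, since any swap reaches it (100 of 100, highest other 1). Genes lower at day 28 had shorter transcripts (median 1248 nt) than genes higher at day 28 (2376.5 nt), but the S phase change was -0.72 with the length and GC trend taken out, -0.79 at no change in library depth and -0.80 at no change in the monocyte, platelet and erythroid scores, against -0.71 before. These values argue against each of the 3 as the whole cause. With no change in the CD4 T cell score as well it was -0.96. The score did not pass over 28 lists, and no biological explanation was tested.

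Oxidative phosphorylation rose with the cell cycle score across patients (r = 0.72 at day 21). The partial r was 0.843 given each library's length and GC slopes, 0.688 given immediate early and heat shock scores as signs of cell handling, and 0.670 given the marker scores of monocytes, platelets and erythroid cells. These values argue against each as the whole cause at day 21. At day 28 the partial r was 0.506, 0.567 and 0.606, and the call there rested on 2 patients: without them r was 0.39 (adjusted p = 0.0707). With the CD4 T cell score added to the marker scores the partial r was 0.465 at day 21 and 0.512 at day 28. At day 21, 7 of the 9 genes of that score had a negative r past the threshold with the cell cycle score, CD4 itself among them (-0.45). The score may not measure the share of CD4 T cells alone. Mean values at day 21 were 7682 for CD5 and 2837 for TNFRSF25, against 339 for CD4. A difference in that share stays open as part of the relation, and this score cannot settle it. Patients were not grouped by any label, so no biological explanation was tested.

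The last pattern concerns 2 lists whose relation may come from their make-up. A candidate explanation for the cytotoxic relation is the naive to effector axis: given the naive and central memory score, r at day 21 was -0.019 (permutation p = 0.908) against 0.57 before. The cytotoxic score thus had no detectable relation to proliferation beyond the naive score. The naive score given the cytotoxic score was not computed, so these values do not tell which of the 2 carries the relation. For the glucocorticoid list, quiescence genes such as TXNIP and PIK3IP1 could have carried the relation. FKBP5, TSC22D3, PER1, ZBTB16 and DDIT4 alone had r = -0.483 at day 21 (permutation p = 0.00246). The relation at day 21 was thus not confined to genes such as TXNIP and PIK3IP1. Whether these 5 genes follow quiescence themselves was not tested, so quiescence and a glucocorticoid response were not told apart. Of these 5, TSC22D3 (-0.61) and DDIT4 (-0.42) passed on their own at day 21, while FKBP5 (-0.29), PER1 (-0.30) and ZBTB16 (-0.30) did not; at day 28 only ZBTB16 passed (-0.45), and FKBP5 (0.06) and PER1 (0.05) lay near 0. At day 28 the cytotoxic r given the naive score was 0.160 and the r of the 5 genes together -0.363 (permutation p = 0.384 and 0.0408). Given the marker scores with that of CD4 T cells, r of the glucocorticoid list at day 21 was -0.30 (adjusted p = 0.171), so the call ended with a smaller r. At day 28 the relation of this list stayed past the threshold with the same scores given. A difference in the share of CD4 T cells stays open, and the CD4 T cell score, which may not measure that share alone, cannot settle it. Differences in steroid dose between patients stay open too, since no label gives treatment.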
